A study of Mus musculus with 12 samples.

How the data were processed

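Whole ovaries of 12 samples were profiled, 7 WT and 5 CKO. Per the labels, polyadenylated RNA was isolated and sequenced as paired-end libraries, and the authors trimmed the reads, aligned them to mm10 with TopHat2 2.0.13, computed and normalized FPKM with Cufflinks 2.2.1 and compared the groups with Cuffdiff 2.2.1 at default settings. The gene annotation, the scaling method and the use of strand are not given in the sources used here. The deposited table holds 1 row per gene symbol, FPKM in 12 sample columns, and the authors' log2 fold change, p-value and q-value. The deposited log2 fold change equals CKO over WT, within 0.01, in 99.9% of 13045 genes with a mean above 1 FPKM, although its name gives the opposite order. Its p-values and q-values come from the authors' Cuffdiff run and were used only for the comparison of calls.

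Columns were assigned to samples by the name in the sample labels. For 1 WT column the name matches the labels of more than 1 WT sample, so it entered as a WT library without a number, called the unnumbered WT library. Genotype groups come from the sample titles.

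FPKM are not counts, and the depth of the libraries is not given. Relative depth was taken from the steps between values of genes with all FPKM below 1, which were whole multiples of the smallest value, within 0.1, in 84.4% of 1560 genes. The value of 1 fragment came from 269 genes with a single annotated transcript, of known length. The upper quartile of FPKM was between 12.9 and 13.2 in all 12 libraries, and the correlation of log2 values across genes had a median of 0.955 between WT, 0.954 between CKO and 0.919 between WT and CKO libraries. No pair of libraries was a duplicate, since the highest correlation was 0.970. A value of 0 can be a failed estimate. In every library, 12 of 80 ribosomal protein genes and 9 of 75 respiratory chain and ATP synthase genes are listed at 0, and Gapdh lies between 1.06 and 7.05 FPKM. Genes listed at 0 in some libraries are therefore given as ranges.

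Values were analysed as log2(FPKM + 1) with R 4.3.3. Genes with FPKM of at least 1 in at least 5 of the 12 libraries were tested (13168 genes) with limma 3.58.1 (trended empirical Bayes, group as the only term), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. On simulated data for these 13168 genes with 200 changed, 78% of genes changed by 1 and 93% of those changed by 2 on the log2 scale were recovered, and 3.9% of calls were unchanged genes. Of simulated unchanged lists of 15 genes, 3% had an exact permutation p under 0.05. Simulated genes were drawn independently with the same SD in both groups, so these rates do not cover correlated members or unequal spreads.

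Before the data were examined, 21 gene lists were fixed from textbook markers, covering oocytes, granulosa, Sertoli, theca and luteal cells, metabolic and signalling pathways, other ovarian cell types, neighbouring tissues and immediate-early genes. A list score is the mean log2(FPKM + 1) of the members tested. Scores of the 19 lists with at least 3 such members were compared by an exact two-sided permutation test over all 792 splits into 7 and 5 libraries, adjusted over the 19 lists, and p = 0.0013 is the smallest this test can give. Camera with a preset correlation of 0.01 and with an estimated correlation served as alternatives. It asks a different question, whether the members changed more than all other genes. Calls over all genes are given beside calls adjusted over the list alone.

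The genes named were set by a rule fixed at the same time: Mtor, the 6 highest and 6 lowest log2 fold changes among called genes whose groups do not overlap and that have an established symbol, the 4 members with the smallest p of each of the oocyte, granulosa, Sertoli, theca and luteal lists, and 2 of each other list. Members named beyond this rule were chosen after their values were seen, and 1 gene that the rule names is not reported here. Positions are from GENCODE M21 on mm10, which gave a single position for 60 of the 61 named genes. Alternatives fixed in advance covered the pseudocount, the filter, 3 scalings, sample weights, an exact Wilcoxon test, a fold threshold, list statistics, clustering choices, leaving out each library and a replicate block. Alternatives with the immediate-early score as a covariate, without the unnumbered WT library and CKO replicate 1, without CKO replicates 2 and 3, and without CKO replicates 1 and 5 were chosen after seeing the data.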

Results

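Gene expression was measured by RNA sequencing of whole mouse ovaries on a C57BL/6 background. Ovaries lacking the kinase Mtor in oocytes, through deletion by a Cre recombinase under the Gdf9 promoter (CKO, n = 5 libraries), were compared with wild-type ovaries (WT, n = 7 libraries). All mice were 6 months old and had received 5 IU of equine chorionic gonadotropin, a hormone that drives follicle growth, 46 h before collection. The deposited values are FPKM (fragments per kilobase of transcript scaled to the mapped fragments of the library) for 24255 genes. Between 14945 and 16083 genes had a value above 0 in a library. Total counts were not used here, but steps between low values put the depth of the 12 libraries within a 2.18-fold range. Relative to WT replicate 1, depth was 1.097 ± 0.209 in WT (SD, n = 7) and 1.137 ± 0.306 in CKO (SD, n = 5). A single fragment on a 1 kb transcript was worth 0.299 to 0.652 FPKM, so values below about 1 FPKM rest on few fragments. The labels give separate samples without animal identities, so p-values measure the spread between these libraries.

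No difference in Mtor RNA of the whole ovary was detected between the genotypes. Mtor (chromosome 4, 148448611 to 148557683, plus strand, mm10) was at 4.70 ± 0.702 FPKM in WT (SD, n = 7) and 5.02 ± 0.499 FPKM in CKO (SD, n = 5). WT libraries lay between 3.84 and 5.55 FPKM and CKO libraries between 4.63 and 5.88 FPKM. The exact two-sided permutation test of these values gave p = 0.4053, and the limma estimate of the log2 fold change was 0.08 with an SE of 0.12. The deletion is restricted to oocytes, and other ovarian cells retain the gene, so a gene-level value of the whole organ does not check the genotype labels.

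**Figure D1:**
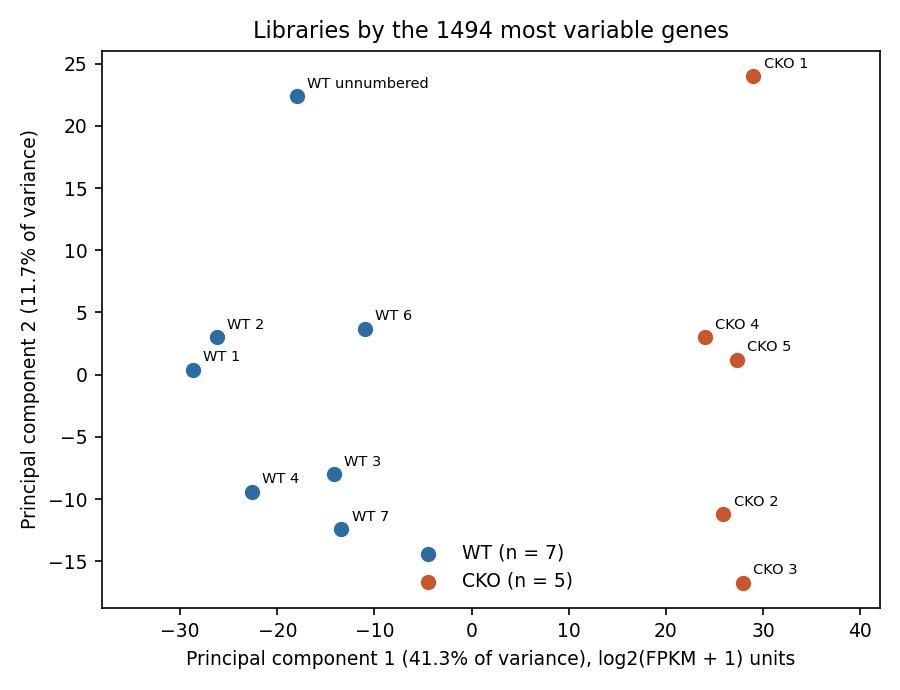
Principal components of log2(FPKM + 1) over the 1494 most variable genes, 1 point per library, WT in blue (n = 7) and CKO in orange (n = 5). The first component, 41.3% of the variance, places all WT libraries at -11 or lower and all CKO libraries at 24 or higher, while the unnumbered WT library and CKO replicate 1 lie apart from the others on the second component, 11.7% of the variance.

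The CKO ovaries carried lower levels of transcripts of oocytes, granulosa cells and dividing cells, and higher levels of transcripts of macrophages and the stromal matrix. The scores of these 5 lists passed the exact permutation test, and with camera and an estimated correlation none of the 5 passed (adjusted p = 0.3248 for oocyte and 0.1504 for each of the other 4). Of 13168 genes tested, 1145 were higher and 999 lower in CKO at an adjusted p under 0.05 (limma on log2(FPKM + 1), Benjamini-Hochberg). Of these, 378 were higher and 313 lower by at least 1 on the log2 scale. The values of the genotypes did not overlap in 1018 of the genes tested, or 7.7%, against 0.25% given by chance. Clustering and the first principal component separated the genotypes, with 12 of 12 libraries in the branch of their group. The authors' deposited table lists 1076 genes higher and 882 lower in CKO at q under 0.05, and 1461 of its calls, 74.8% of those among the genes tested here, were also called here in the same direction, with 0 in the opposite direction. Of 9 immediate-early genes, which respond within minutes to stimuli and handling, 5 were higher in CKO, while their list score did not pass (adjusted p = 0.1 in the exact permutation test). With this score as a covariate, a setting chosen after seeing the data, the calls numbered 454 higher and 372 lower. Without CKO replicates 1 and 5, which had high levels of blood transcripts, they numbered 702 higher and 673 lower, a setting likewise chosen after seeing the data. Both settings make the genotype estimates less precise. The covariate was itself higher in CKO (8.0 against 6.26 in WT), and the other setting leaves fewer libraries. Fewer calls therefore do not by themselves show smaller differences.

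Among called genes with an established symbol whose genotypes did not overlap, the 6 largest rises were in Cma1, Fcer1a, Serpina3n, Tpsb2, Mmp12 and Gpnmb. Cma1, a mast cell chymase (chromosome 14, 55941451 to 55944675, minus strand), ranged from 0 to 5.53 FPKM in WT and from 18.9 to 111 FPKM in CKO. Fcer1a, a chain of the IgE receptor (chromosome 1, 173221284 to 173227214, minus strand), was listed at 0 in 5 of 7 WT libraries and lay between 9.80 and 34.9 FPKM in CKO. Tpsb2, a mast cell tryptase (chromosome 17, 25366305 to 25369098, plus strand), was at 2.94 ± 2.10 FPKM in WT (SD, n = 7) and 42.9 ± 28.2 FPKM in CKO (SD, n = 5). The other rises were in Serpina3n, a serine protease inhibitor (chromosome 12, 104406729 to 104414329, plus strand), Mmp12, the macrophage elastase (chromosome 9, 7344381 to 7369499, plus strand), and Gpnmb, a lysosomal membrane glycoprotein (chromosome 6, 49036546 to 49070929, plus strand). Their log2 fold changes were 3.71, 2.92 and 2.86, with SE of 0.59, 0.45 and 0.44. The 6 largest falls among such genes were in Apoa4, Inhbb, Nap1l5, Ihh, Zar1 and Slc38a3. Inhba, whose genotypes overlapped, had a log2 fold change of -4.14 with an SE of 0.58 (adjusted p = 0.000505, limma), and was named after its values were seen. Slc38a3, an amino acid transporter (chromosome 9, 107650634 to 107669530, minus strand), lay between 8.86 and 28.2 FPKM in WT and between 0 and 1.58 FPKM in CKO. Apoa4, an apolipoprotein (chromosome 9, 46240696 to 46243459, plus strand), was at 51.4 ± 36.0 FPKM in WT (SD, n = 7) and 4.01 ± 6.38 FPKM in CKO (SD, n = 5). In CKO replicate 1 it was at 15.4 FPKM, and without that library its log2 fold change moved from -3.82 to -4.42. The adjusted p (limma) of the 12 genes without overlap lay between 1.8e-05 and 0.00105.

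**Figure D2:**
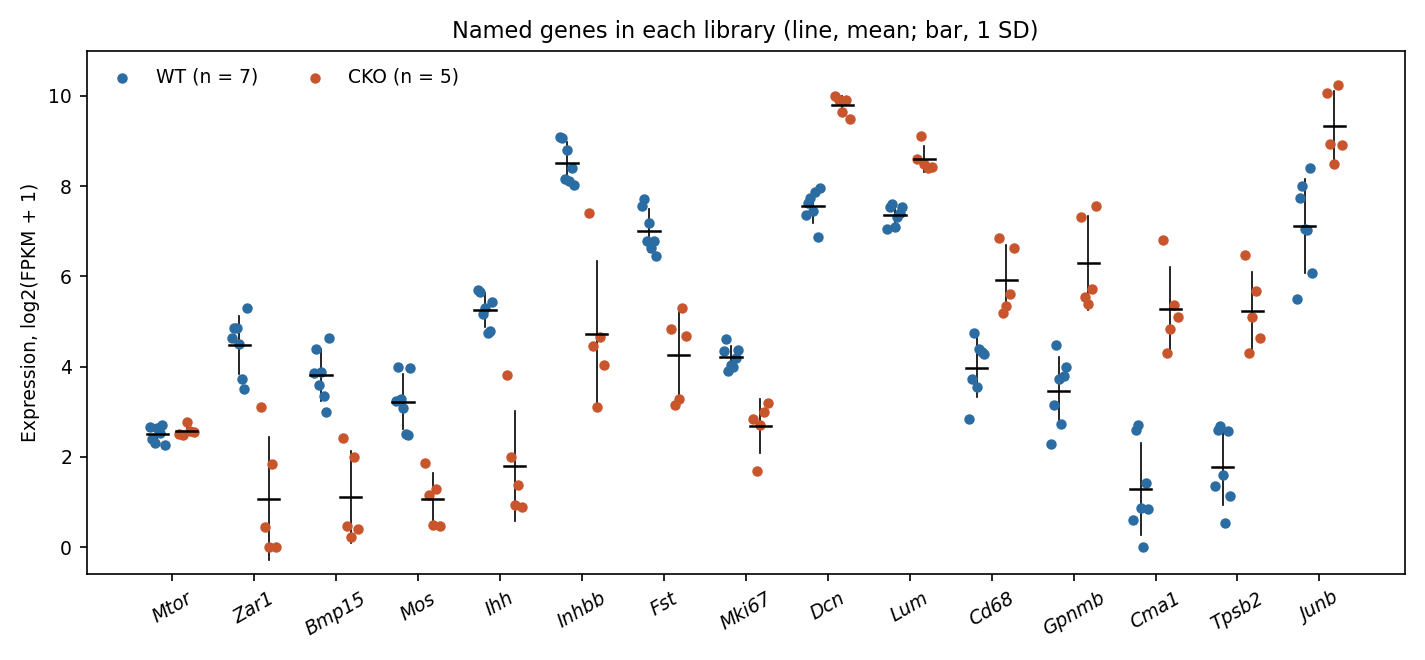
Expression of 15 genes in each library on a log2(FPKM + 1) axis, WT in blue (n = 7) and CKO in orange (n = 5), with the group mean as a line and 1 SD as a bar. Mtor overlaps between the genotypes, Zar1, Bmp15, Mos, Ihh, Inhbb, Fst and Mki67 lie lower in CKO, and Dcn, Lum, Cd68, Gpnmb, Cma1, Tpsb2 and Junb lie higher.

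Most oocyte transcripts fell in CKO. Of 27 oocyte genes in the list, 21 could be tested, 13 fell and 0 rose (14 fell when adjusted over the list alone). Bmp15, a growth factor secreted by oocytes (chromosome X, 6314107 to 6320721, minus strand), was at 14.1 ± 5.98 FPKM in WT (SD, n = 7) and 1.65 ± 1.92 FPKM in CKO (SD, n = 5). Mos, the kinase of the meiotic arrest (chromosome 4, 3870657 to 3872105, minus strand), was at 9.10 ± 4.26 FPKM and 1.23 ± 0.93 FPKM. Zar1, a maternal factor of early cleavage (chromosome 5, 72576806 to 72581254, minus strand), lay between 10.3 and 38.2 FPKM in WT and between 0 and 7.56 FPKM in CKO. Obox5, an oocyte homeobox gene, lay between 3.17 and 8.84 FPKM in WT and between 0 and 1.64 FPKM in CKO. Other members did not pass the test, among them Nobox at 2.53 ± 1.12 FPKM in WT (SD, n = 7) and 3.51 ± 2.97 FPKM in CKO (SD, n = 5), and Nlrp5 at 9.25 ± 3.79 FPKM and 9.5 ± 5.22 FPKM, both named after their values were seen. The list score, the mean log2(FPKM + 1) of the members, was 2.93 ± 0.47 in WT (SD, n = 7) and 1.68 ± 0.62 in CKO (SD, n = 5), with p = 0.0038 in the exact two-sided permutation test (adjusted p = 0.0144 over 19 lists). With camera and an estimated correlation of the members the adjusted p was 0.3248. Without CKO replicates 2 and 3, which had high levels of the oviduct gene Ovgp1, the score difference was -1.04 with adjusted p = 0.0528 in the exact permutation test, and without CKO replicates 1 and 5 it was -1.27 with adjusted p = 0.0633, both settings chosen after seeing the data. With all 12 libraries the difference was -1.25. Leaving out 2 libraries leaves fewer than 792 splits, so the smallest exact p is above 0.0013. A lost threshold alone therefore does not show a smaller fall.

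Granulosa cell transcripts fell in CKO. Of 20 granulosa genes, 16 fell and 0 rose (17 fell when adjusted over the list alone), and Amhr2, Grb14, Kctd14 and Ccnd2 did not pass. Inhbb, the beta-B subunit of inhibin and activin (chromosome 1, 119415465 to 119422248, minus strand), was at 384 ± 124 FPKM in WT (SD, n = 7) and 47.1 ± 67.5 FPKM in CKO (SD, n = 5). In CKO replicate 1 it was at 167 FPKM, and without that library its log2 fold change moved from -3.79 to -4.46. Ihh, a hedgehog ligand of growing follicles (chromosome 1, 74945315 to 74951672, minus strand), was at 38.4 ± 10.0 FPKM and 3.90 ± 5.25 FPKM. It was at 13.2 FPKM in CKO replicate 1, and its log2 fold change moved from -3.46 to -3.96 without that library. Fst, which encodes the activin antagonist follistatin (chromosome 13, 114452290 to 114458951, minus strand), was at 135 ± 47.1 FPKM and 21.4 ± 13 FPKM. Nr5a2, a nuclear receptor of granulosa and luteal cells, was at 177 ± 55.3 FPKM and 37.4 ± 16.4 FPKM, and Nap1l5 was at 271 ± 96.3 FPKM and 29.1 ± 34.8 FPKM. The adjusted p of these 5 genes lay between 0.000272 and 0.000529 (limma). The score was 6.58 ± 0.36 in WT (SD, n = 7) and 4.73 ± 0.54 in CKO (SD, n = 5), with exact permutation p = 0.0013, the smallest that the 792 splits can give, and adjusted p = 0.006. With an estimated correlation, camera gave an adjusted p = 0.1504.

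Transcripts of dividing cells were lower in CKO. Of 18 proliferation genes, 14 fell and 0 rose (14 when adjusted over the list alone). Mki67, a marker of cycling cells (chromosome 7, 135689784 to 135716361, minus strand), was at 17.7 ± 3.29 FPKM in WT (SD, n = 7) and 5.82 ± 2.24 FPKM in CKO (SD, n = 5). Aurkb, a mitotic kinase (chromosome 11, 69045647 to 69051664, plus strand), was at 12.4 ± 1.74 FPKM and 4.34 ± 1.16 FPKM. The 4 members that did not pass were Mcm5, Mcm6, Pcna and Tyms, genes of DNA replication and nucleotide synthesis, while Mcm2 and Rrm2, of the same functions, fell. The score was 3.44 ± 0.24 in WT (SD, n = 7) and 2.45 ± 0.38 in CKO (SD, n = 5), with exact permutation p = 0.0013 and adjusted p = 0.006. Camera with an estimated correlation gave an adjusted p = 0.1504.

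Markers of Sertoli cells, the somatic cells of the testis, were included because ovaries without oocytes can express some of them. Their score did not pass the test. Of 17 genes, 11 could be tested, Cyp26b1 and Cldn11 rose and Dhh fell (the same 2 rises and 1 fall when adjusted over the list alone). Dhh, a hedgehog ligand that granulosa cells also make, was at 16.3 ± 5.70 FPKM in WT (SD, n = 7) and 6.14 ± 1.90 FPKM in CKO (SD, n = 5). Cyp26b1, an enzyme that degrades retinoic acid, was at 4.46 ± 2.54 FPKM and 11.2 ± 5.50 FPKM, and Cldn11, a tight junction protein, at 10.5 ± 4.66 FPKM and 17.3 ± 1.5 FPKM. The calls for Cyp26b1 and Cldn11 were lost in 7 and 8 of the 12 fits that leave out 1 library. Defb19, a defensin, did not pass (adjusted p = 0.142, limma). Dmrt1, a regulator of testis identity, was listed at 0 in all 12 libraries, and Sox9 did not pass, at 1.48 ± 0.83 FPKM and 2.53 ± 1.29 FPKM. The score was 3.41 ± 0.20 in WT (SD, n = 7) and 3.60 ± 0.34 in CKO (SD, n = 5), exact permutation p = 0.2538.

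Theca and luteal transcripts, which mark the steroid-producing compartments, did not pass the test as groups. Of 14 theca and steroidogenic genes, Por rose and Stard4 fell, also when adjusted over the list alone (1 and 1). Por, the electron donor of cytochrome P450 enzymes, was at 24.8 ± 3.60 FPKM in WT (SD, n = 7) and 40.3 ± 8.10 FPKM in CKO (SD, n = 5). Stard4, a cholesterol carrier, was at 27.9 ± 11.5 FPKM and 13.1 ± 4.35 FPKM, a call lost in 10 of the 12 fits that leave out 1 library. Ptch1 did not pass (adjusted p = 0.0754, limma), except without WT replicate 6 or CKO replicate 2 (adjusted p = 0.044 and 0.0284). Cyp17a1, named after its values were seen, was at 95.8 ± 85.2 FPKM and 17.7 ± 8.51 FPKM and did not pass (adjusted p = 0.193, limma). It was at 1.46 FPKM in the unnumbered WT library and between 41.2 and 267 FPKM in the other WT libraries. All CKO libraries lay between those, from 7.95 to 30.2 FPKM. Of 10 luteal genes, Parm1 fell, from 31.7 ± 9.72 FPKM in WT (SD, n = 7) to 9.39 ± 3.78 FPKM in CKO (SD, n = 5), also when adjusted over the list alone (1 gene). Hsd17b7, an enzyme of luteal estradiol and cholesterol synthesis, was at 577 ± 326 FPKM and 145 ± 90.8 FPKM without passing the test (adjusted p = 0.245, limma). In the unnumbered WT library it was at 11.5 FPKM, and without that library its log2 fold change moved from -1.66 to -2.47 and passed (adjusted p = 0.0029). Timp1 and Cited4 did not pass, except without CKO replicate 4 for Timp1 (adjusted p = 0.0331) and without CKO replicate 1 for Cited4 (adjusted p = 0.0495). None of the 18 cholesterol synthesis genes passed (0, and 0 adjusted over the list alone), while Dhcr7 and Pmvk passed without the unnumbered WT library (adjusted p = 0.0164 and 0.0168, limma). The exact permutation p of the scores was 0.1578 for theca, 0.9104 for luteal and 0.3434 for cholesterol synthesis genes. The luteal score difference was -0.07 while the median log2 fold change of its members was 0.08. In the unnumbered WT library these scores were 6.03, 5.07 and 4.34, below the other 6 WT libraries, and without it the theca score difference moved from -0.35 to -0.52 and passed the threshold, and the luteal one moved to -0.41.

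**Figure D3:**
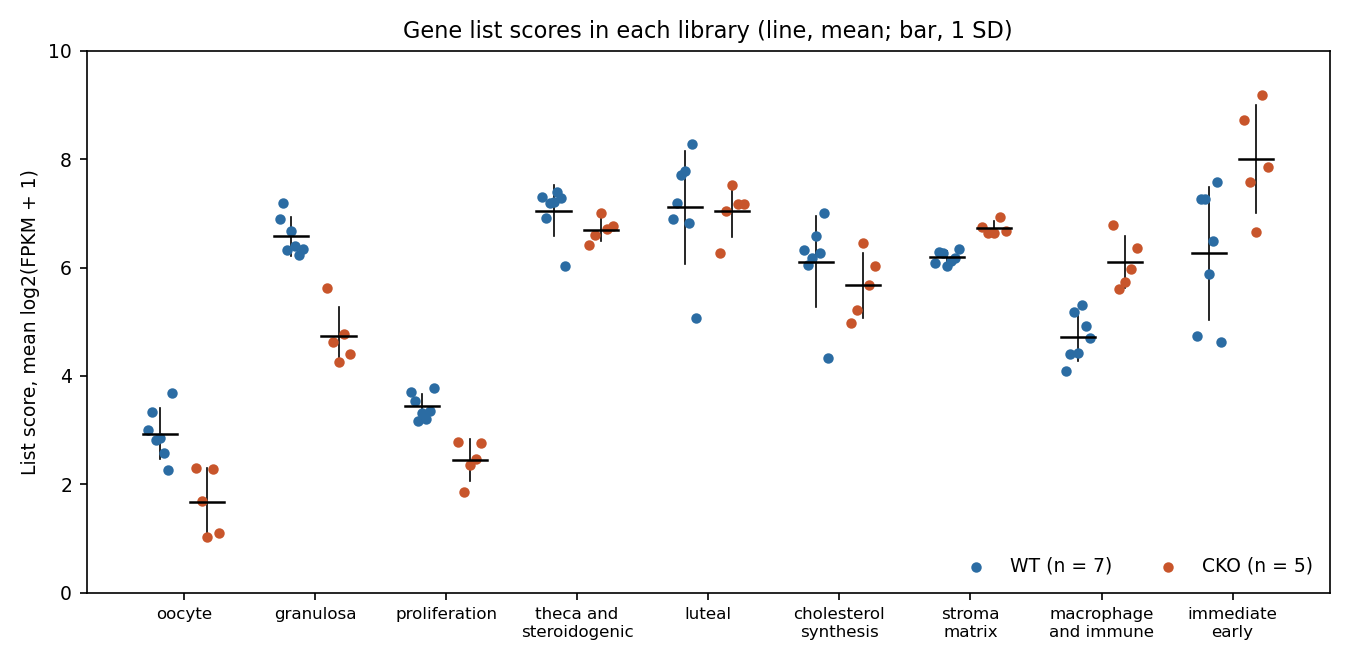
Scores of 9 gene lists in each library (mean log2(FPKM + 1) of the members past the filter), WT in blue (n = 7) and CKO in orange (n = 5), with the group mean as a line and 1 SD as a bar. Oocyte, granulosa and proliferation scores are lower in CKO, stroma matrix and macrophage scores are higher, and the lowest WT point for theca, luteal and cholesterol synthesis genes, at 6.03, 5.07 and 4.34, is the same library.

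Stromal matrix transcripts rose in part. Of 14 genes, Dcn, Lum, Mgp, Tcf21 and Ogn rose and 0 fell (7 rose when adjusted over the list alone). Dcn, which encodes the proteoglycan decorin (chromosome 10, 97479609 to 97518143, plus strand), was at 191 ± 45.0 FPKM in WT (SD, n = 7) and 892 ± 129 FPKM in CKO (SD, n = 5). Lum, which encodes lumican (chromosome 10, 97565128 to 97572703, plus strand), was at 165 ± 24.8 FPKM and 396 ± 88.3 FPKM. Fibrillar collagen genes did not pass over all genes, although Col5a1 is among the 7 adjusted over the list alone. Col1a1 was at 19.8 ± 4.31 FPKM and 28.5 ± 9.73 FPKM, and both were named after their values were seen. The score was 6.18 ± 0.12 in WT (SD, n = 7) and 6.73 ± 0.13 in CKO (SD, n = 5), exact permutation p = 0.0013 and adjusted p = 0.006, and camera with an estimated correlation gave an adjusted p = 0.1504. Among 7 smooth muscle genes none passed (0, and 0 adjusted over the list alone), with Des and Myh11 at adjusted p = 0.0701 and 0.12 (limma), and Des at 0.0216 without CKO replicate 2. Of 10 endothelial genes, 9 were tested and Tek, the angiopoietin receptor, rose (1 also adjusted over the list alone), from 6.75 ± 1.55 FPKM in WT (SD, n = 7) to 10.4 ± 1.27 FPKM in CKO (SD, n = 5), a call lost in 2 of the 12 fits that leave out 1 library, while Pecam1 did not pass. Of 10 surface epithelium genes, 8 were tested and Krt19, a keratin, rose (1 also adjusted over the list alone), from 25.3 ± 13.2 FPKM to 56.2 ± 37.1 FPKM, a call lost in 8 of the 12 fits that leave out 1 library. Krt18 did not pass. The exact permutation p of these 3 scores was 0.1667, 0.2083 and 0.173.

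Macrophage and immune transcripts rose almost throughout the list. Of 16 genes, 15 were tested and 13 rose (15 when adjusted over the list alone), and Adgre1 and Tyrobp did not pass over all genes. Gpnmb was at 11.2 ± 5.99 FPKM in WT (SD, n = 7) and 96.8 ± 70.2 FPKM in CKO (SD, n = 5). Cd68, a lysosomal glycoprotein of macrophages (chromosome 11, 69664213 to 69666153, minus strand), was at 16 ± 6.67 FPKM and 67.1 ± 36.2 FPKM. Both genes and the list score were highest in CKO replicates 1 and 5, the libraries with the highest blood scores, with Gpnmb at 159 and 187 FPKM and list scores of 6.79 and 6.36. The other 3 CKO libraries had list scores of 5.61 to 5.98, against 5.30 or less in WT, and without CKO replicates 1 and 5 the score difference was 1.06 with adjusted p = 0.0396 in the exact permutation test. The score was 4.72 ± 0.44 in WT (SD, n = 7) and 6.10 ± 0.48 in CKO (SD, n = 5), exact permutation p = 0.0013 and adjusted p = 0.006. Camera with an estimated correlation gave an adjusted p = 0.1504. With the immediate-early score as a covariate the score differences were 1.02 for macrophage, 0.48 for stroma matrix, -1.28 for oocyte, -1.998 for granulosa and -0.90 for proliferation genes, each still past the threshold. A permutation test with this covariate is approximate, since the covariate itself was higher in CKO.

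Metabolic and signalling lists showed few calls or none. Among 17 genes of the Mtor pathway, Mlst8, a subunit of both Mtor complexes, fell from 18.8 ± 1.48 FPKM in WT (SD, n = 7) to 14.9 ± 1.56 FPKM in CKO (SD, n = 5), a call lost in 7 of the 12 fits that leave out 1 library, and Eif4ebp2 did not pass (adjusted p = 0.0552, limma), except without CKO replicate 2 or 3 (adjusted p = 0.0403 and 0.0252). Of 15 glycolysis genes tested, Aldoc, an aldolase, fell from 5.75 ± 2.05 FPKM to 2.87 ± 1.07 FPKM, a call lost in 7 of those fits, and Tpi1 did not pass. Neither list had a call when adjusted over the list alone (0 and 0). Of 80 genes with a ribosomal protein symbol, 55 were tested and Rps6 rose, a call lost in 10 of those fits, with 0 adjusted over the list alone. Of 75 genes in the respiratory chain list, which also holds ATP synthase genes, 62 were tested. Ndufa3 rose, and Atp5o and Atp5j2, both of ATP synthase, fell, with 0 rises and 1 fall adjusted over the list alone. The Atp5j2 call was lost in 5 of the 12 fits. Many copies of such genes share reads with pseudogenes, and 12 ribosomal protein genes were listed at 0 in every library, so single values in these lists are uncertain. Of 9 genes induced around ovulation, 6 were tested and none passed (0, and 0 adjusted over the list alone), including Ereg and Ptx3. The exact permutation p of the scores was 0.654 for the Mtor pathway, 0.2917 for glycolysis, 0.9924 for ribosomal protein, 0.4331 for respiratory chain and 0.2184 for ovulation genes. With the median over members in place of the mean, the Mtor pathway difference was -0.195 instead of -0.016 and passed (adjusted p = 0.0144, exact permutation test). The ribosomal score difference, 0.001, changed sign under upper-quartile scaling and quantile normalization.

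Lists for handling and for neighbouring tissues were measured in the same libraries. Of 9 immediate-early genes, Fos, Jun, Junb, Egr1 and Ier2 rose (5 also when adjusted over the list alone). Junb was at 168 ± 106 FPKM in WT (SD, n = 7) and 720 ± 388 FPKM in CKO (SD, n = 5), and Jun at 207 ± 112 FPKM and 560 ± 255 FPKM. The score was 6.26 ± 1.22 in WT (SD, n = 7) and 8.0 ± 1.0 in CKO (SD, n = 5), exact permutation p = 0.0316 and adjusted p = 0.1, and camera with an estimated correlation gave an adjusted p = 0.5222. Malat1, a nuclear long noncoding RNA, was at 408 ± 127 FPKM in WT (SD, n = 7) and 820 ± 155 FPKM in CKO (SD, n = 5) and rose (adjusted p = 0.00401, limma). Rn45s, the ribosomal RNA precursor, was at 2496 ± 592 FPKM and 4940 ± 2156 FPKM and did not pass (adjusted p = 0.0538, limma), both named after their values were seen. Ovgp1, which encodes oviductin, was at 252 FPKM in CKO replicate 2 and 81.9 FPKM in CKO replicate 3 and at 1.88 FPKM or less in the other 10 libraries. It was not called (adjusted p = 0.0517 over all genes, 1 rise adjusted over the list alone), and Tppp3, the other oviduct gene tested, was not either. Foxj1 (4.72 and 1.48 FPKM) and Pax8 (2.36 and 1.06 FPKM), low and not tested, were also highest in CKO replicates 2 and 3. Elsewhere they were at 0.6 and 0.378 FPKM or less. Tppp3, Dnah5 and Ccdc39 were not highest in both of these libraries. Ovgp1 passed without CKO replicate 1, 4 or 5 (adjusted p = 0.035, 0.0307 and 0.0329, limma), and Tppp3, lower in CKO, without CKO replicate 1 (adjusted p = 0.022). Without those 2 CKO libraries 941 genes were higher and 714 lower. Of 7 adipose genes, 2 were tested (1 rise and 1 fall, also adjusted over the list alone). Fabp4, which endothelial cells and macrophages also express, rose from 6.08 ± 2.20 FPKM in WT (SD, n = 7) to 29.7 ± 17.4 FPKM in CKO (SD, n = 5), and Plin1, a lipid droplet protein, fell from 6.87 ± 3.55 FPKM to 3.18 ± 1.2 FPKM, a call lost in 10 of the 12 fits that leave out 1 library, while Adipoq was at 0.68 FPKM or less in every library. Of 8 blood genes, 5 were tested and none passed (0, and 0 adjusted over the list alone), with scores of 6.22 and 6.21 in CKO replicates 1 and 5 and of 4.03 or less in the other 10 libraries (exact permutation p = 0.197). Hbb-bt and Hba-a1, which share reads with their paralogs, were at adjusted p = 0.124 and 0.481 (limma), and Hbb-bt at 0.0459 without CKO replicate 2.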

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

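The tests of the unnumbered WT library below were chosen after its values were seen. Within each genotype, 13 values lay further from the other libraries than Dixon's ratio allows, and chance gives about 1 in 20 groups, which over the 160 groups examined is several. The value below is a list score or a log2(FPKM + 1).

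Among WT, the unnumbered library was lowest for several steroidogenic transcripts, with a theca and steroidogenic score of 6.03 (next lowest WT library 6.92), a cholesterol synthesis score of 4.34 (next 6.04), Hsd17b7 at 3.65 (next 8.51) and, outside steroidogenesis, Tek at 2.26 (next 2.88). A CKO library under a WT name is argued against by its granulosa score of 6.35, above the highest CKO score of 5.62, and its oocyte score of 3.68, above the highest CKO score of 2.30. Shallow sequencing is argued against by its relative depth of 1.315, the highest of the WT libraries. A smaller share of luteal tissue as the only difference is argued against by Cyp17a1, an enzyme of theca cells, at 1.46 FPKM where the other 6 WT libraries lie between 41.2 and 267 FPKM, a test moved there from Cyp19a1 (1.26 FPKM, others 28.8 to 88.9 FPKM) after that value was seen, since luteal cells can express Cyp19a1. A different response to the hormone or a different stage of the cycle may account for the pattern and was not tested, as the labels give neither.

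The remaining values are given without explanation. In CKO replicate 1, Nap1l5 was 6.53 (next 4.08) and Krt19 6.94 (next 5.50). In CKO replicate 2 the glycolysis score was 4.33 (next 4.86). In CKO replicate 3, Mtor was 2.78 (next 2.57). In CKO replicate 4, Pecam1 was 5.90 (next 5.55) and Plin1 1.06 (next 2.10). In WT replicate 1 the blood score was 4.03 (next 2.96). In WT replicate 3, Fcer1a was 1.30 (next 0.53) and Defb19 4.19 (next 5.51).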

How the results depend on the processing

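Settings with a covariate or with several libraries left out were chosen after seeing the data. Direction and side of the threshold held for the oocyte, granulosa, proliferation, stroma matrix and macrophage scores under both pseudocounts, both filters, 3 scalings and each left-out library. Leaving out each library in turn gave 893 to 1200 genes higher and 737 to 1106 lower in CKO, and 1321 of the 2144 calls held in all 12 fits, with 0 changing sign. In those fits the log2 fold change of Mtor ranged from 0.03 to 0.12.

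The score differences in those fits ranged as follows, with the lowest value first: oocyte -1.41 to -1.09, granulosa -2.07 to -1.72, Sertoli 0.07 to 0.29, theca -0.52 to -0.28, luteal -0.41 to 0.125, cholesterol synthesis -0.73 to -0.27, glycolysis -0.154 to 0.000186, Mtor pathway -0.051 to 0.007, ovulation 0.15 to 0.56, proliferation -1.07 to -0.84, ribosomal protein -0.088 to 0.087, respiratory chain -0.125 to 0.003, stroma matrix 0.49 to 0.57, smooth muscle 0.235 to 0.57, endothelium 0.12 to 0.32, macrophage 1.21 to 1.5, surface epithelium 0.16 to 0.59, blood 0.64 to 1.72 and immediate-early 1.44 to 2.08. The luteal difference changed sign without WT replicate 3, 4 or 7 or CKO replicate 1 (0.029, 0.042, 0.125 and 0.121), the ribosomal one without WT replicate 2, 3 or 4 or CKO replicate 1 or 5 (-0.014, -0.003, -0.014, -0.088 and -0.063), the Mtor pathway one without CKO replicate 1, and the glycolysis and respiratory ones without CKO replicate 2. The theca score passed the threshold without the unnumbered WT library and the immediate-early score (2.08, adjusted p = 0.0384) without CKO replicate 3.

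The counts moved by over 1.5 times in a few settings. An exact Wilcoxon test called 749 genes higher, and a log2 fold change of at least 1 left 378 higher and 313 lower by construction. With the immediate-early score as a covariate 454 were higher and 372 lower, and Ereg (-0.023), Ptx3 (-0.154) and the Mtor pathway (0.027), ovulation (-0.142), ribosomal (-0.054) and endothelium (-0.049) scores changed sign. That covariate was itself higher in CKO, which costs precision, so the lower counts alone do not show smaller differences. For same-numbered WT and CKO libraries the correlation of their deviations was between -0.071 and 0.09 over 4 pairs. Among these, 1 CKO and 2 WT libraries correlated best with their own number. Within each genotype the numbers follow the sorted order of the names in the sample labels, so a shared number does not mark a pair. Neither this correlation nor the block on these numbers can therefore show whether libraries share a batch or litter. The replicate block, fitted to the 8 libraries numbered 1 to 4, called 756 higher and 622 lower, against 901 and 707 in the same libraries without it. With 4 pairs the exact paired p cannot go below 0.125, so the oocyte (-1.18), granulosa (-1.95), proliferation (-1.06), stroma matrix (0.58) and macrophage (1.504) scores could not pass. The ribosomal score difference changed sign with the block (-0.025).

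Camera values are the mean log2 fold change of the members minus that of all other genes, so they are not score differences. With an estimated correlation the oocyte (-1.27, adjusted p = 0.325), granulosa (-1.86), proliferation (-1.002), stroma matrix (0.53) and macrophage (1.37) lists did not pass, the last 4 at adjusted p = 0.15. The ribosomal camera value was -0.011. With a preset correlation the immediate-early list (1.73, adjusted p = 0.000167) passed, which it did not with an estimated one (adjusted p = 0.5222), and the ribosomal value was -0.011. The median over members turned the luteal (0.005), glycolysis (0.22) and endothelium (-0.048) differences, and the Mtor pathway (-0.20) passed. The ribosomal difference turned with a pseudocount of 0.1 (-0.026), upper-quartile scaling (-0.00027) and quantile normalization (-0.065). Without the unnumbered WT library and CKO replicate 1, theca (-0.45) passed, and the Mtor pathway (0.005) and ribosomal (-0.077) values turned. Without CKO replicates 2 and 3, oocyte (-1.04) no longer passed, ovulation (0.82), smooth muscle (0.81) and blood (2.50) passed, and glycolysis (0.021) and respiratory chain (0.000494) turned. Without CKO replicates 1 and 5, 702 genes were higher, oocyte (-1.27, adjusted p = 0.0633) no longer passed, and luteal (0.14), Mtor pathway (0.021), ribosomal (-0.202) and blood (-0.269) differences and Hba-a1 (-0.197) turned. Leaving out 2 CKO libraries also raises the smallest exact p, so the oocyte score can lose the threshold without a smaller difference. Except where a count above or the construction shows it, the cause was not tested. For named genes, 1423 values in all settings kept direction and side, 141 lost the threshold, 46 gained it and 3 changed sign. Depth limits values below about 1 FPKM.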

Other observations

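The 3 immune lists in this paragraph were added after the data were seen, and they share members such as Gpnmb with the fixed macrophage and immune list. Of 10 mast cell genes, 8 were tested and 6 rose, and the list score was 1.46 ± 0.31 in WT (SD, n = 7) and 3.66 ± 0.47 in CKO (SD, n = 5), exact permutation p = 0.0013. Hdc and Kit, which other ovarian cells also express, were at 22.3 ± 9.74 FPKM and 6.42 ± 2.71 FPKM in WT and did not pass. Of 11 lysosome-rich macrophage genes, 10 rose. They include Atp6v0d2, a proton pump subunit, at 6.88 ± 3.17 FPKM in WT and 52.1 ± 32.4 FPKM in CKO, and Ctsd, which most cells express, at 471 ± 61.9 FPKM and 1215 ± 447 FPKM. Ctsk did not pass. A plasma and B cell list did not pass the test (exact permutation p = 0.1477), with Igj higher and Derl3 lower among its 4 genes tested. Since these lists were written around genes already seen to rise, their counts are not independent evidence.

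The tests reported from here on were chosen after the result was seen, apart from the count of splits. Of 100 splits of the 12 libraries into 7 and 5, the real one included, 1 gave as many genes as the real 2144. That was the real split, and the highest other split gave 420. Chance alone is therefore unlikely, although 100 splits cannot give a share below 1 in 100. The count cannot separate genotype from a factor that differs between the same groups, such as handling.

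Macrophage and immune transcripts were higher in CKO. Loss of granulosa RNA, raising every other cell type alike, is argued against: the macrophage score rose by 0.99 more than the mean of endothelium, smooth muscle and stroma matrix scores (exact permutation p = 0.0051). A handling response as the whole cause is argued against too: with the immediate-early score as a covariate the difference was 1.02 against 1.38 without it, with a permutation p = 0.0013 over all 792 splits of the group labels, the smallest these can give. This p is approximate, since most splits do not keep the higher immediate-early score of CKO (exact permutation p = 0.0316, adjusted p = 0.1). That immune cells are more numerous in CKO ovaries, or express more of these genes, stays open as hypotheses that RNA of the whole ovary does not separate and that counts of stained or sorted immune cells would test.

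A list of 8 genes, called early-stage oocyte genes here, was added after the data were seen. These data do not show which cells or oocyte stages express them. Without the filter their mean log2(FPKM + 1) was 1.14 ± 0.20 in WT (SD, n = 7) and 1.25 ± 0.54 in CKO (SD, n = 5), exact permutation p = 0.6023. Over the 5 genes past the filter it was 1.55 ± 0.26 and 1.53 ± 0.61 (exact permutation p = 0.9356), with a fall of Taf4b. Levels too low for a fall to show were first tested against 9 other oocyte genes in the same range of WT means, whose score difference was lower by 1.21 (-1.21, exact permutation p = 0.0013), which would argue against that explanation. That test was replaced after its result was seen, because the 9 genes had a higher WT score (2.0 against 1.14). In the replacement, 4 of the early-stage genes were matched within 1.5 times in WT mean to Zp1, Npm2, Oosp1 and Padi6, whose score difference was lower by 0.51 (-0.51, exact permutation p = 0.0871), so a floor and a true difference between the sets cannot be told apart with 4 pairs. Single genes did not all follow the division of the sets: Taf4b fell, while Nlrp5 and Dppa3, among the other oocyte genes, did not pass (adjusted p = 0.976 and 0.322, limma). RNA of the whole ovary also does not separate fewer oocytes from lower levels within them. That oocytes of primordial follicles may be retained while growing ones are lost is a hypothesis that these data leave open and that follicle counts in sections would test.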
